A study of Homo sapiens with 8 samples.

How the data were processed

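RNA was sequenced from HEK-293T cells, a transformed human embryonic kidney line that takes up plasmids readily, after transfection with an empty vector, GFP, PARN or the D28A form of PARN. PARN is a deadenylase, an exonuclease that shortens poly(A) tails. The labels describe a cytosolic and an endoplasmic reticulum (ER) fraction of each sample, separated by stepwise detergent extraction, Trizol RNA and a stranded library kit. There were 8 libraries, 1 for each of the 4 constructs in each of the 2 fractions. Each library was given its construct and fraction from its title, such as flag-C or P74-M. In these titles flag was read as empty vector, C as cytosol and M as the ER fraction. P74 was read as PARN from the series design. No construct and fraction had a replicate, so no error, no test and no p-value of a re-analysis could be given, and every difference below compares 2 libraries.

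Per the submitters' processing notes, cutadapt, Trimmomatic 0.36, STAR and Cuffdiff were used with the genome build hg38. Versions of the other tools, their settings, the annotation release, the expression filter and the use of strand in counting are not given in the sources used here. The deposited data came as 5 tables. In 3 of them the authors listed gene symbols only, selected at a log2 fold change above 1 or above or below -1 per the file headers, or the symbols shared by such lists. The other 2 tables held Cuffdiff rows for the genes left by the authors' filters, 8 in the ER fraction and 38 in the cytosol. Expression in these rows was in FPKM as deposited by the authors, that is, scaled by transcript length and library. The log2 fold changes were those deposited by the authors, of the second library over the first with no pseudocount. The p-value and q-value columns were also deposited by the authors and come from 1 library on each side, so they rest on a modelled spread, not on measured replicate error. Sequencing depth is unknown, since the tables hold no counts and FPKM could not be turned back into reads.

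Each Cuffdiff run compared 2 libraries and was scaled on its own. For the 8 ER genes the empty vector FPKM of the D28A run was 0.982 times that of the PARN run, and for the 38 cytosol genes the median factor was 1.06. PARN and D28A were therefore compared through the shared empty vector library, as the D28A log2 fold change minus the PARN log2 fold change. Counts of genes with a difference of at least 2-fold used log2(FPKM + 1) and genes with at least 1 FPKM in either library, as fixed before the data were examined. This scale understates the change of low genes. The genes with values had been chosen by the authors for log2 fold changes below -1 with PARN and, for all 38 cytosol genes and 6 of the 8 ER genes, above -1 with D28A, so their directions are not independent evidence. Lists without values allow no such count and no median log2 ratio. The comparison of GFP with empty vector within a fraction was not analysed here, because GFP enters the tables only as an ER over cytosol list.

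Some list entries had been turned into calendar dates, 21 distinct ones, and were left out. The 14313 remaining distinct names were matched to GENCODE release 29 for position, type, length and GC content, with the longest transcript standing for the gene. Of these, 12733 matched by symbol and 283 through a synonym in RefSeq, which is 90.9% of the names. Coordinates are given on hg38, counted from 1. In the list of names lower with PARN in the cytosol 78.0% of names had annotation, under the 80% set as the minimum, so GC and length checks of that list as a whole are void and GC values involving it are given for its 598 protein-coding genes.

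The order of names in the PARN and D28A lists was checked against the deposited log2 fold changes. Every gene with a value stood in order of its log2 fold change in all 4 lists, 8 and 38 genes in the PARN lists and 6 and 38 in the D28A lists. The D28A lists were then read as ranked by log2 fold change, with genes of known value as bounds. This order was inferred from those genes and is not stated in the sources used here. It is unchecked before the first and past the last such gene of each list. In the cytosol PARN list the last was ALKBH8, at place 859 of 978 with a log2 fold change of -1.004.

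19 gene lists with 469 genes were fixed before the data were examined. They cover the unfolded protein response, ER chaperones, ER translocation, cholesterol synthesis, secreted and matrix proteins, integrins and adhesion receptors, solute carriers, p53 targets, AU-rich and immediate early mRNAs, deadenylation and decay factors, telomerase and telomere genes, ribosomal proteins, glycolysis, histones, mitochondrial mRNAs, nuclear-retained RNAs, interferon-stimulated genes, heat shock proteins and the cell cycle. Members in a deposited list, or their median position in a ranked one, were set beside 10000 random lists of the same size, as a description of these libraries. Matching on expression was not possible without values. As an alternative chosen after seeing the data, random lists were matched within 10 bins of GC content and 3 bins of transcript length. Of 108 such comparisons, 31 lay outside the central 95% of random lists and 26 outside that of matched ones, against 5.4 by chance. None of those outside came from the lists of names lower with PARN. On a simulated order of 13016 genes the procedure singled out 40 of 40 planted lists and 1 of 40 unrelated ones.

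Overlaps were compared with n1 × n2 / N. The background N was all names in any list or the 10181 names listed in both fractions. The second background lacks genes that lay at or below -1 with D28A and above -1 with PARN. 6 pairs of lists were each computed under 9 settings, all chosen after seeing the data, among them protein-coding genes alone and expected overlaps summed over 20 bins of GC content or length. On simulated lists with opposite GC trends over 13016 genes and no other relation, the mean ratio was 0.580 without bins and 1.01 within GC bins. With 200 shared names planted it was 1.25 within bins. PARN and D28A share 1 empty vector library per fraction. Unchanged libraries were therefore simulated for 1000000 genes with equal normal noise, fitted to the share of names below -1 with PARN or 4 times as wide. This simulation was added after seeing the data and decides nothing. The D28A share was held to its 2 limits by its exact interval, a rule also set after seeing the data, under which the verdict went from argued against to open.

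Genes named in the report were to follow a rule fixed before the data were examined. It took PARN first, the 10 largest and 10 smallest log2 ratios among genes with values, and 2 to 4 members of each fixed gene list with the largest absolute log2 ratio. It also took all genes of an authors' final list of up to 30, otherwise the 15 with the largest fall against empty vector. Most gene-list members had no value, so those named were not chosen by the rule. The small RNAs and names shared by longer lists were named outside it. Some members of the gene lists are not reported here by name. The part of the rule on log2 ratios could only run within the genes the authors kept. Other pseudocounts, minimum values and backgrounds were tried. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.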

Results

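The screen asked which mRNAs were lowered by PARN at the ER and which in the cytosol of HEK-293T cells. An empty vector and GFP served as control transfections, and the D28A form of PARN served as a comparison for the active enzyme. Each of the 4 constructs was sequenced once in each of the 2 fractions, which gave 8 libraries without replicates. No difference below could therefore be set against replicate error. Depth is unknown, and most genes appear only as members of lists selected by the authors, with FPKM for 46 genes.

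PARN itself, encoded on chromosome 16 from 14435701 to 14632728 on the minus strand (ENSG00000140694), was examined first. Its transcript stood near the top of both ranked lists for D28A, at place 102 of 12315 in the cytosol and place 91 of 11041 in the ER fraction. In the cytosol this place lay above that of RGS5, whose log2 fold change was 1.41 in the authors' deposited table. In the ER fraction it lay above ADGRL3, at 0.30 in the authors' deposited table. RGS5 and ADGRL3 are the first genes with a value in these lists, so the order at the places of PARN is unchecked. PARN was in neither list of names lower with PARN. No FPKM for PARN was given in the tables, so its level with the PARN plasmid could not be checked.

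The first comparison asked which transcripts were at least 2-fold higher in the ER than in the cytosolic fraction of each control. With empty vector the authors listed 2653 entries and with GFP 3340. All 13 mitochondrially encoded mRNAs, among them MT-CO1 and MT-ND1, were in both lists. ER-enriched thus means higher in the fraction labelled ER, and does not show that an mRNA was bound to the ER. Of 20 ER chaperones and folding enzymes, 15 were ER-enriched with empty vector and 12 with GFP, 7 of them in both, including HSPA5 (BiP) and HSP90B1. Solute carriers and ion pumps gave 18 and 15 of 23, such as SLC38A2. Integrins and adhesion receptors gave 14 and 12 of 18, such as ITGB1 and NRP1. Components of ER translocation and glycosylation gave 11 and 12 of 23, including SEC63 and STT3A, and unfolded protein response genes 12 and 12 of 29. For cholesterol synthesis genes the numbers were 10 and 8 of 23, with SQLE and INSIG1 in both lists. All these counts lay above the central 95% of random lists of the same size, except cholesterol synthesis with GFP (random range 2 to 9). When random lists were matched on GC content and length, the translocation count with GFP also lay within their range, 5 to 12. Ribosomal protein mRNAs numbered 2 and 3 of 43, below the random ranges of 3 to 13 and 5 to 16 but not below the matched ones, which began at 2 and 3.

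For the remaining groups, too, no difference between the controls was tested. Secreted and matrix genes numbered 23 of 27 with empty vector, including FN1 and SPARC, where random lists held 1 to 9. With GFP they numbered 10, including FN1 and LAMB1, within the random range of 2 to 11 and above the matched range of 1 to 7. Deadenylation and decay factors numbered 1 of 41 with empty vector (EDC4), below the random range of 3 to 13. With GFP 18 were listed, among them CNOT7, DCP2 and DDX6, above the random range of 4 to 15 but within the matched range of 10 to 20. Cell cycle genes gave 1 and 9 of 28, with MKI67 in both, and glycolysis genes 3 and 0 of 17, including PFKL and ALDOA. The count of 1 and the count of 0 lay below the random ranges, 2 to 9 and 1 to 7, but within the matched ones. Within the random range for both controls lay heat shock genes at 1 and 6 of 14, p53 targets at 3 and 7 of 23 with MDM2 and FAS in both, and telomere genes at 2 and 4 of 17 with TERC in both. Histones gave 5 and 2 of 19 with HIST1H4C in both, interferon-stimulated genes 3 and 1 of 10 including IFI6 with empty vector, and AU-rich and immediate early mRNAs 2 and 3 of 27. Of nuclear-retained RNAs 1 and 2 of 4 were listed, with MALAT1 in both, and no random range was computed for so few members.

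The 2 control lists shared 416 names, where unrelated lists among 14313 names would share 616. They also differed in base composition. Among protein-coding genes the median GC content of the longest transcript was 56.9% in the empty vector list and 41.5% in the GFP list, beside 49.4% for all names. In the quintile of genes with the lowest GC content 8.03% were ER-enriched with empty vector and 63.3% with GFP. In the quintile with the highest GC content these shares were 36.6% and 0.418%. Within bins of GC content the overlap was 1.28 times the expected number, against 0.676 times without bins.

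**Figure D1:**
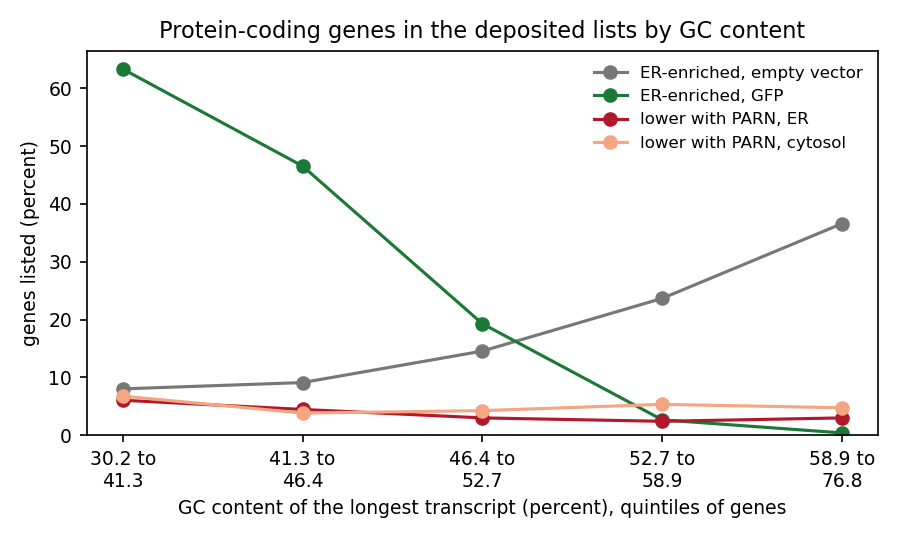
Share of protein-coding genes in 4 deposited lists (vertical axis, percent) in quintiles of the genes ordered by GC content of the longest transcript (horizontal axis, percent). Each point is the share of the genes of that quintile. The empty vector list goes from 8.03% to 36.6% and the GFP list from 63.3% to 0.418%, while the lists of names lower with PARN stay between 2.43% and 6.78%.

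The second comparison asked which transcripts of the ER fraction were at least 2-fold lower with PARN than with empty vector. The authors listed 634 entries, of which 632 were usable names and 454 were protein-coding. The small nuclear RNA 7SK (RN7SK), which regulates transcription elongation, stood first in this list, before the first gene with a value, where the order is unchecked. Members of the fixed gene lists were scarce, at 6 of 369, where random lists of that size held 13 to 30. Random lists were not matched on expression or gene type. Lists matched on GC content and length held 12 to 28. The PARN-lower list was 71.8% protein-coding, against 88.0% of all names listed in the ER fraction. This gap could account for part of the scarcity at most, and how large a part was not tested. These 6 were SEC63 of the translocation machinery, the p53 target MDM2, the telomerase RNA TERC, the histone HIST4H4, the interferon-stimulated IFI27 and the heat shock gene HSPA1A. None of the ER chaperones, secreted proteins, adhesion receptors, solute carriers, cholesterol genes or decay factors was listed, and neither were unfolded protein response, AU-rich, ribosomal protein, glycolysis, mitochondrial, nuclear-retained or cell cycle members. Where a random range was computed for a single list, it began at 0 and held the observed count, so no single absence stood out. Of the 632 names, 341 (54.0%) were above a log2 fold change of -1 with D28A, and the other 291 were not listed there. None of the 6 gene-list members was among the 341.

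The 39 names that were ER-enriched in both controls and lower with PARN included 15 above -1 with D28A. The 8 genes with values all came from these 39 names. MDM2, the ubiquitin ligase that limits p53 (chromosome 12, 68808176 to 68850686), had 4.94 FPKM with empty vector and 0.690 FPKM with PARN, 7.15-fold lower. ST3GAL6, a sialyltransferase (chromosome 3, 98732236 to 98821201), was 6.87-fold lower, at 2.53 and 0.368 FPKM. VPS50, an endosomal recycling factor (chromosome 7, 93232340 to 93361121), was 8.82-fold lower, at 1.396 and 0.158 FPKM. The zinc finger gene ZNF385B (chromosome 2, 179441982 to 179861505) was 6.21-fold lower, the peptidase DPP8 (chromosome 15, 65442463 to 65517704) 4.76-fold lower and the DNA repair nuclease gene MRE11A (chromosome 11, 94415578 to 94493908) 4.32-fold lower. The adhesion receptor ADGRL3 (chromosome 4, 61201258 to 62078335) was 2.36-fold lower and the Hedgehog receptor PTCH1 (chromosome 9, 95442980 to 95517057) 2.33-fold lower. Across the 8 genes PARN values ranged from 0.158 to 1.39 FPKM.

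With D28A, 7 of the 8 ER genes were also below empty vector. MDM2 was 2.22-fold lower and VPS50 2.78-fold lower with D28A, past the 2-fold limit in both cases, whereas ADGRL3 was 1.23-fold higher. The authors' deposited row of VPS50 with D28A was marked as not tested. Selection below -1 with PARN and above -1 with D28A holds for 6 of the 8 genes, so that for these the direction of D28A against PARN was fixed by the filter. D28A exceeded PARN in all 8 genes by a log2 difference of 0.91 (PTCH1) to 2.05 (ST3GAL6), with a median of 1.68. The difference was above 1.5, the limit named in a file header, for 6 of 8. MDM2 (1.69) and VPS50 (1.67), below -1 with D28A, were among these, so their direction may have been selected too. The lowest q for PARN in the authors' deposited table was 0.105, for MDM2 with p = 0.00015, and the lowest q for D28A was 0.9996. On log2(FPKM + 1), 5 of 7 genes were at least 2-fold lower with PARN, 0 of 8 with D28A, and 0 of 7 with PARN against D28A, since values near 1 FPKM are compressed on that scale. With a pseudocount of 0.1 these became 7 of 7, 2 of 8 and 6 of 7.

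**Figure D2:**
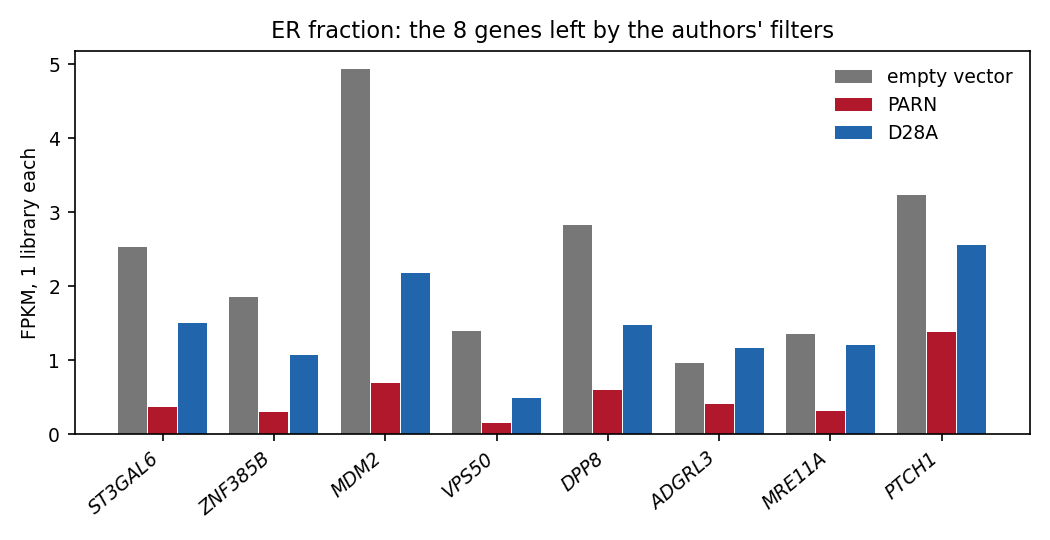
FPKM in the ER fraction (vertical axis) of the 8 genes left by the authors' filters (horizontal axis), with 1 library per bar and no error bars because there were no replicates. Empty vector values are those of the run with PARN. PARN bars lie below the other bars for every gene, from 0.158 to 1.39 FPKM, and ADGRL3 is the gene whose D28A bar lies above empty vector.

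The third comparison put the same question to the cytosol, where 978 entries were at least 2-fold lower with PARN. Of the 977 usable names 598 were protein-coding. The fixed lists contributed 18 of 357 members, against 18 to 37 in random lists. Interferon-stimulated genes gave 3 of 10 (ISG15, IFI6 and IFI27), at the upper end of the random range of 0 to 3. Cholesterol genes gave 3 of 22 (TM7SF2 and STARD4 among them), solute carriers 3 of 16 (SLC3A2, SLC16A1 and ATP1B1), secreted genes 2 of 22 (COL4A2 and SPARC), adhesion receptors 2 of 9 (ITGA6 and CADM1) and histones 2 of 8 (HIST1H2BJ and HIST1H2BN). The stress kinase EIF2AK3, the signal peptidase subunit SPCS3 and the immediate early gene FOSB were the single members of their lists, and EIF2AK3 was the only 1 of 23 from the unfolded protein response. No member was listed for ER chaperones, p53 targets, decay factors, telomere genes, ribosomal proteins, glycolysis, mitochondrial mRNAs, nuclear-retained RNAs, heat shock or the cell cycle. Random ranges of single lists, where computed, began at 0 here too and held every count. Above -1 with D28A were 413 of the 977 names, or 42.3%, among them 8 of the 18 gene-list members. This split went with base composition. The median GC content was 42.9% for the 280 protein-coding names above -1 with D28A and 54.2% for the 318 not listed there. Whether GC content or the active enzyme set the split was not tested.

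FPKM were given for 38 of these genes, all lower with PARN than with empty vector by selection. MATR3, a nuclear matrix RNA-binding protein (ENSG00000280987, chromosome 5, 139273752 to 139331671), showed the largest gap, 5.02 FPKM with empty vector against 0.121 with PARN and 12.6 with D28A. This gene model overlaps a second protein-coding MATR3 gene on the same strand, between which reads can be divided, so its values are uncertain. The testis kinase TSSK4 (chromosome 14, 24205697 to 24208362) was 13.96-fold lower with PARN, and GPR89A (chromosome 1, 145607990 to 145670648), which has a near-identical copy, 8.05-fold lower. BARD1, the partner of BRCA1 (chromosome 2, 214725646 to 214809711), had 5.07 FPKM with empty vector and 1.07 with PARN, 4.73-fold lower. The next largest margins below empty vector were 4.46-fold for WDR66, 4.41-fold for the cytokine IL11, 4.24-fold for the kinase CDKL1, 4.19-fold for DOCK9, 3.95-fold for the laminin chain LAMA3 and 3.88-fold for TTC37. Smaller ones followed for CCDC14 (3.53-fold), SGK3 (3.46-fold), the BMP receptor BMPR1A (3.37-fold), the urea cycle enzyme CPS1 (3.34-fold) and the SUMO protease SENP5 (3.32-fold). WDR66 and SGK3 overlap other coding genes on the same strand. The smallest gaps were 2.01-fold for ALKBH8 and 2.03-fold for TTC39B, and AKAP10 and RGS5 stood at 2.16- and 2.17-fold.

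With D28A, 29 of the 38 cytosol genes were above empty vector and 5 at least 2-fold, namely RGS5 (2.66-fold), MATR3 and CDKL1 (both 2.37-fold), ALKBH8 (2.15-fold) and BMPR1A (2.03-fold). BARD1 had the lowest D28A log2 fold change, -0.77. All 38 genes had been selected below -1 with PARN and above -1 with D28A, so D28A above PARN was fixed by the filter. The sizes were bounded by selection too, since 35 of the 38 differences lay above the 1.5 named in a file header and the lowest was 1.47. The median log2 difference among these selected genes was 1.80, from 1.47 for BARD1 to 6.62 for MATR3. After MATR3 the widest were GPR89A (3.80), TSSK4 (3.53), CDKL1 (3.33), BMPR1A (2.77), WDR66 (2.75), RGS5 (2.53) and IDNK (2.28). The narrowest, besides BARD1, were TMEM106B (1.48) and CPS1 (1.49). No q in the authors' deposited table was below 0.698 for PARN or 0.998 for D28A. On log2(FPKM + 1) the genes at least 2-fold apart were 7 of 37 for PARN against empty vector, 3 of 38 for D28A against empty vector and 17 of 36 for PARN against D28A. With a pseudocount of 0.1 the first and last of these became 36 of 37 and 36 of 36.

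**Figure D3:**
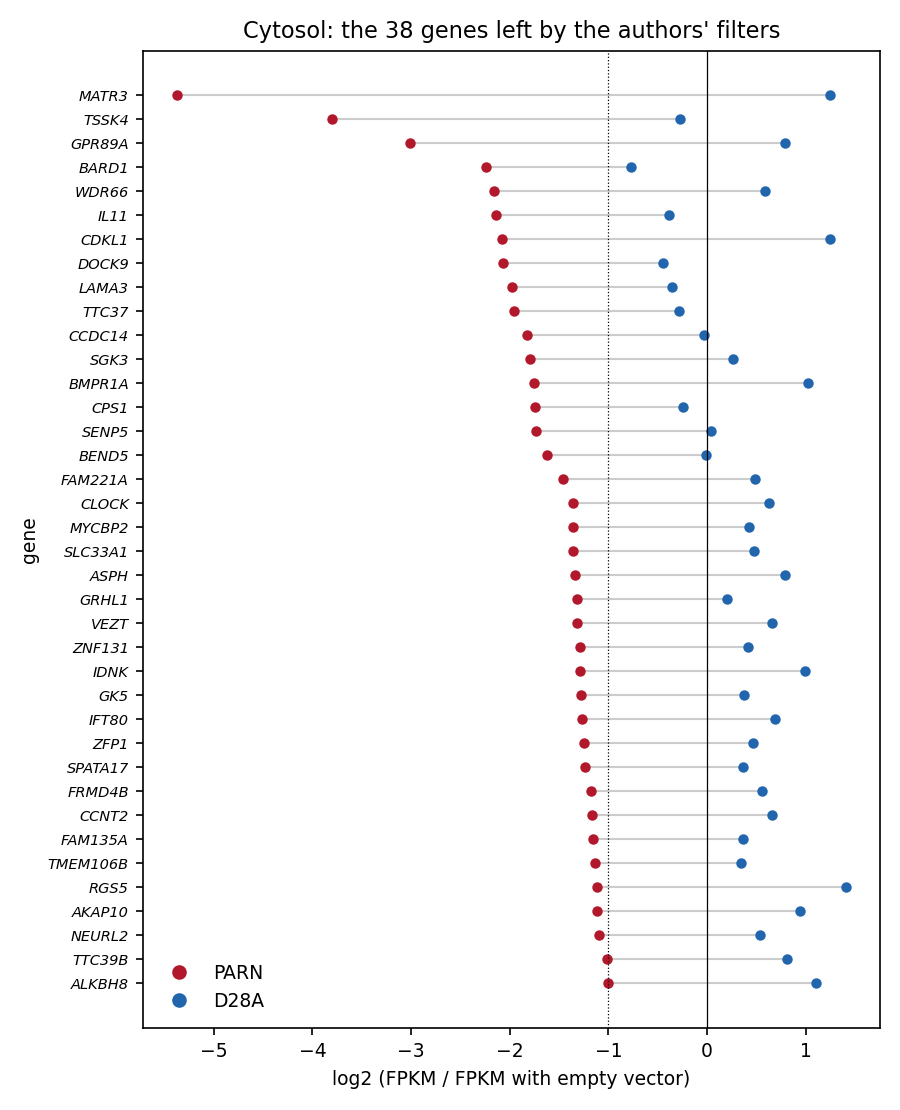
log2 fold change over empty vector in the cytosol (horizontal axis) of the 38 genes left by the authors' filters (vertical axis), for PARN and D28A, 1 library each, joined by a line per gene. The dotted line marks -1. PARN points run from -5.37 to -1.004 and D28A points from -0.77 to 1.41.

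The ER and cytosol target lists, 8 and 38 genes, shared 0 genes, where 0.0212 would be shared by unrelated lists. All 8 ER genes were ER-enriched in both controls, which held for only 3 of the 38, so the filters left little room for overlap. Among the 38, CPS1, GK5, IL11, SLC33A1 and VEZT were also listed as lower with PARN in the ER fraction. The absence of shared genes thus does not show separate targets. Longer lists of names lower with PARN and above -1 with D28A, 102 also ER-enriched with empty vector and 413 in the cytosol, shared 4, namely ANLN, COX6B2, NDOR1 and PIGN, beside 2.94 for unrelated lists. Without the request for ER enrichment, 341 and 413 names shared 15 against 9.84, VEZT among them.

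D28A was compared with empty vector through the ranked lists, which hold names above -1 only. In the cytosol between 1026 and 1088 of 12315 entries were at least 2-fold higher with D28A, and between 6041 and 6508 were higher at all. ER chaperones lay low, with a median place of 89.6% from the top, below those entries. P4HB and FKBP10 stood near the end, past the last gene with a value, where the order is unchecked. ERO1A and HSP90B1 went the other way, at places 280 and 807, among the entries read as at least 2-fold higher. The place of ERO1A lies before RGS5 at 456, the first gene with a value, so it is unchecked. Solute carriers stood at 81.6% (SLC7A5 and SLC1A5 low, but SLC39A10 at 9.71% and SLC38A2 at 9.87%), mitochondrial mRNAs at 82.7% and histones at 87.8%. Cholesterol genes stood at 70.7%. These 5 medians lay outside the central 95% of random lists and of matched ones, whereas heat shock genes at 25.6% lay within both. ER chaperones, solute carriers and mitochondrial mRNAs were also over-represented among the ER-enriched names of both controls. How cleanly the fractions of each library separated was not tested. Their low places therefore do not show that D28A lowered these mRNAs. Decay factors stood at 27.5% with PARN, the transfected gene, counted and at 28.95% without it. XRN1 and CNOT6 stood high, but BTG2, TOE1 and EDC3 stood at 85.0% to 91.1%. Both medians lay outside the range of random lists. Without PARN the median lay within the matched range of 28.90% to 53.5%. In the ER fraction entries higher with D28A numbered between 2942 and 7697 of 11041. AU-rich and immediate early mRNAs lay at 82.2%, with FOSB and BTG2 near the end but PLAU at 7.67% and DUSP4 at 15.3%. Ribosomal proteins at 30.6% and glycolysis genes at 26.5% stood nearer the top. These 3 medians lay outside both random ranges. Heat shock genes at 76.8% and decay factors at 67.5% left the range of random lists but not that of matched ones. The reverse held for p53 targets in the ER fraction at 28.4% and ER translocation genes in the cytosol at 65.8%, which left the matched range alone. The orders of the 9734 names in both lists had a Spearman rho of -0.053 across genes, which are not independent replicates. Place and GC content were related across genes too, with rho = -0.51 in the cytosol and 0.25 in the ER fraction, where a positive value means higher with D28A at higher GC content.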

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

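The overlap settings, longer target lists, protein-coding counts, matched random lists and decay factors without PARN were chosen after seeing the data; the other alternatives were fixed before. With a pseudocount of 0.1, genes at least 2-fold apart became 36 of 37 for PARN against empty vector in the cytosol, 2 of 8 for D28A against empty vector in the ER, 6 of 7 for PARN against D28A in the ER and 36 of 36 in the cytosol, because adding 1 compresses values near 1 FPKM. A minimum of 5 FPKM left 2 of 2 cytosol genes for PARN against empty vector and 3 of 3 against D28A, and no ER gene. Other counts stayed within 1.5 times under these settings and without a minimum. The target overlap of 0 became 4 and 15 with the longer lists. Within GC bins the overlap of the control lists reversed to 1.28 times expected and that of the PARN-lower ER list with the GFP list to 0.996. With names listed in both fractions as background, the overlap of PARN-lower lists was 4.08 times expected. Protein-coding names lower with PARN in the cytosol numbered 598. With GFP in place of empty vector, the ER-enriched members of 10 of 19 gene lists moved by over 1.5 times. The causes were not tested unless stated. Centring the ratios was not run, as genes selected for low PARN values have no neutral median. GFP as control in other comparisons, all alternatives for GFP against empty vector, and pseudocounts or minimum values for gene lists were not run for lack of values. No paired analysis was possible because no gene had values in both fractions. Unknown depth limits every low FPKM.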

Other observations

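The tests against the GFP list and of the D28A share below, the cytosol overlaps set beside them, the simulation and the protein-coding form of the GC test of names lower in both fractions, were chosen after the result was seen. The other GC and length tests were set before their values were known, but after the median GC content of each list had been seen.

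Small structured RNAs were found in both lists of names lower with PARN; they were picked out after their values were seen. In the ER list RN7SK stood at place 1, SNORD13 at 5, SCARNA12 at 19, SCARNA13 at 94, RNU4-1 at 123 and TERC, the telomerase RNA, at 235. RN7SK, SNORD13 and SCARNA12 lie before VPS50 at place 29, the first gene with a value, where the order is unchecked. Of 11 such RNAs in the ER list 5 were above -1 with D28A in that fraction, namely RN7SK, SCARNA12, SCARNA13, RNU4-1 and SNORA71D. The others, SNORD13, SNORA11, SNORA12, SNORA31, RNU5B-1 and TERC, were not listed there. In the cytosol list 5 of 20 were above -1 with D28A. All 11 small RNAs of the ER list were also ER-enriched with empty vector. RN7SK, SCARNA12, SNORA12, SNORA71D, RNU5B-1 and TERC were ER-enriched with GFP too, and the rest were not. The empty vector ER library enters both comparisons, and whether their fall with PARN rests on that library was not tested. Nor was their share of the list set beside that of all names. In the cytosol SNORD13 was at place 907 of 978. This lies past ALKBH8 at place 859, the last gene with a value, whose log2 fold change was already -1.004. The order of that tail is unchecked, so the place does not give the size of the fall. Counted were names annotated as small nuclear, nucleolar, Cajal body, miscellaneous or mitochondrial transfer RNAs, and TERC. Of these SNORD13 and SNORA11 were in both lists, as was RN7SL832P, a 7SL copy annotated as long non-coding and not counted. Several lie within other genes, SCARNA12 within PHB2 and SNORA11 within MAGED2, so reads of host transcripts cannot be excluded.

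The list of transcripts ER-enriched with empty vector was deposited in 2 versions, of which the second is the one used above. The second version begins with the same 2506 entries in the same order and adds 147. Of the added entries 57.8% had clone-style names, against 8.60% of the first version. The authors' first chain of overlaps (102 names) used the first version and their second chain (39 names) the second.

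The ER-enriched lists of the 2 controls shared fewer names than unrelated lists (0.676 times expected). Transcript length is argued against as the cause, since the ratio within length bins was 0.697. GC content is a candidate explanation, since within GC bins the ratio turned to 1.28. A GC-dependent difference between libraries or between detergent extractions may thus separate the control lists. An effect of GFP itself stays open and was not tested.

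Names lower with PARN in the ER fraction were over-represented in the empty vector list of ER-enriched names, at 2.07 times expected, and GC content is argued against as the cause, since the ratio within GC bins was 2.17. The empty vector ER library is in both comparisons, so a chance high value there could place a name in both lists. The ratio for the empty vector list was 1.75 times that for the GFP list over all names but 1.09 times over names listed in both fractions, so that the test as set leaves this explanation open. Chance in the empty vector cytosol library would by the same reasoning deplete names lower with PARN in the cytosol from the empty vector list, and these stood at 0.83 times expected over all names, at 1.66 over names listed in both fractions and at 1.18 among protein-coding genes within GC bins, which settles nothing. For the ER names the GFP list, which shares no library, gave 1.18 over all names and 1.45 over names listed in both fractions. Within GC bins it gave 0.996 and 0.983, beside 2.17 and 1.90 for the empty vector list. A general preference of PARN for ER-enriched mRNAs thus found support in the GFP list without GC bins and none within them. An excess left only in the list that shares the library is also what chance in that library would give. The comparison of the 2 lists within GC bins was not the test as set.

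Names lower with PARN in the ER fraction and in the cytosol overlapped by 94, or 2.18 times expected. The expected number treats all names as equally likely to be listed. Overlaps could not be matched on expression, so the part of expression level in this excess was not tested. Among protein-coding genes, GC content (2.56 within bins) is argued against as the cause, and so are non-coding names (2.69 among protein-coding genes without bins). Of the 94 names 16.0% were above -1 with D28A in both fractions (exact 95% binomial interval 9.22 to 24.95, counting error only), which misses the 34.2% set for a loss that needs the active enzyme and meets the limit set against it, at or below the 22.8% from the separate lists. The share alone would thus argue against such a loss, and it is left open here only because the interval reaches past 22.8%, a rule set after the values were known. PARN and D28A share the empty vector library of each fraction. Simulated unchanged libraries gave 52.8% with noise fitted to the data, above the interval of the observed share. Wider noise gave 19.0%, within that interval, but put 34.5% and 36.0% of genes below -1, unlike the data (5.59% and 7.60% of names). Both settings assume equal noise for all genes, so no conclusion on the shared library is drawn from them. That library, like PARN protein without catalysis, transfection and the cultures, stays open.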
